A study of Mus musculus with 39 samples.

How the data were processed

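RNA was sequenced from 39 libraries in 4 experiments: 10 DC libraries of a time course, 8 DC libraries of a costimulation experiment at 12 h, 15 DC libraries of a 5-replicate experiment at 20 h and 6 OT-II T cell libraries at 20 h. The labels state that DC were enriched by negative selection and sorted, and that libraries were built in plates from captured polyA RNA. According to the submitters' processing notes reads were demultiplexed with bcl2fastq and aligned with HISAT 0.1.6 to the mm9 build, and exon reads were summed per gene with HOMER.

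For DC the authors deposited tables of raw counts per gene, whole numbers with a different total in each library, beside a second block of values. The deposited T cell table holds normalized signal: each value was a whole multiple of 1 step per library, to within 0.01 reads. Counts had thus been divided by a size factor, and whole reads could be recovered. Per the file headers the same tables give a log2 fold change for each comparison, and the authors deposited an adjusted p-value beside it from a DESeq2 analysis. The count tables held 24421, 24421 and 24411 genes and that of T cells held 7830, so a filter that no header states had been applied to it. Labels put 2 libraries in the table of the 5-replicate experiment in no sample, and their 4 columns were not used. The files use mm9 while the reference at hand is a later build, so no coordinates are given.

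Counts of DC were tested with the quasi-likelihood test of edgeR 4.0.16, with TMM normalization, filterByExpr by group and all libraries of an experiment in the model, so that groups of 2 share an estimate of the spread. Genes with an adjusted p (Benjamini-Hochberg) under 0.05 were called. The same test had been planned for the T cells on the assumption of counts. Since that table holds normalized counts, limma 3.58.1 with a trend was used on log2(normalized count + 1), for genes with at least 10 normalized counts in 3 libraries. DESeq2 1.42.0 was run as an alternative throughout. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used. The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except those described as chosen after seeing the data.

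The 34 gene lists cover type I interferon, interferon-gamma, NF-kB, costimulatory ligand, maturation, cytokine, chemokine, MHC class I and II, cell cycle, glycolysis, oxidative phosphorylation, cholesterol, unfolded protein, immediate early and ribosome biogenesis genes. For T cells they cover activation, naive, T helper 1, follicular helper, regulatory and type I interferon genes. Marker lists cover T, CD8 T, B, NK, neutrophil, monocyte, plasmacytoid DC, conventional DC (all, type 1, type 2), Langerhans or migratory DC and stromal cells. Lists with at least 3 measured members were tested with camera on voom values with a preset correlation of 0.01 between genes, with camera and an estimated correlation as the alternative and with fry. Their p-values were adjusted by Benjamini-Hochberg over the lists of a comparison. Genes of a list were also adjusted over the list alone. Some genes stand in more than 1 list.

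Named genes follow a rule. Cd80 and Cd86 are followed in the costimulation experiment. Among called genes with a mean of at least 10 CPM and no overlap between the libraries, the 6 largest rises and 6 largest falls are taken (8 and 8 in OVA against BSA at 20 h and in T cells), leaving out unclear gene models. Up to 4 called members of each list with the smallest adjusted p are added, and in a list called by camera without a called member the 2 of smallest p. Cd40, Cd80, Cd86, Cd83, Ccr7, Il12b, Il15 and Cd274 are always followed in DC, and Cd69, Il2ra, Il2, Myc, Cd40lg, Nr4a1 and Ifng in T cells. The text gives a selection of these genes.

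Replicate numbers were checked for pairing by the correlation of same-numbered libraries, with 0.1 as the level over which a pair counts. Libraries with Y-linked transcripts over 20 CPM were marked. A gene with 0 counts in a group was set to a floor of 3 counts over the group for its bound. Floors cover counting error only. Tests were tried on simulated data with 200 changed genes, drawn at random from genes with an expected count over 10. Each gene was simulated independently of the others. Unchanged groups were simulated in 10 draws for comparisons that share controls. Alternatives were DESeq2, its size factors, no filter on low counts, a mean of at least 1 CPM, the replicate number as a block, only the libraries of the groups compared, and each library left out in turn. For T cells pseudocounts of 0.5 and 5 and edgeR on recovered reads were added after seeing the data, as were a term for Y-linked transcripts and leaving out non-immunized replicate 3 with OVA replicate 3 at 20 h. A count was taken to have moved beyond a factor of 1.5.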

Results

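RNA was sequenced from 39 libraries of sorted mouse lymph node cells in 4 experiments. Dendritic cells (DC), the cells that carry antigen to T cells, came from the popliteal and inguinal nodes of C57BL/6 mice immunized under the skin of the hock with nanoparticles. The particles held CpG, an agonist of Toll-like receptor 9, alone or with ovalbumin (OVA) or bovine serum albumin (BSA). According to the series description the mice carried transferred OT-I and OT-II T cells, whose receptors recognize OVA, and the aim was to record how DC respond early to an encounter with such T cells. The labels of the time course and the 5-replicate experiment do not say per sample whether the mice carried OT cells, so OVA there is an antigen for OT cells only if they did. A time course held 2 libraries each of DC from non-immunized mice and from mice given CpG-only or OVA particles 12 h or 24 h earlier. A costimulation experiment at 12 h held 2 libraries each of 4 groups, which were wild type with OVA and no OT cells, wild type with OVA and OT cells, wild type with BSA and OT cells, and a Cd80/86 knockout with OVA and OT cells. A 5-replicate experiment held 5 libraries each of DC from non-immunized mice and from mice given BSA or OVA particles 20 h earlier. OT-II T cells sorted 20 h after BSA or OVA particles gave 3 libraries per group.

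Total counts per library ran from 612017 to 1329203 in the time course, from 628404 to 1621784 in the costimulation experiment and from 367209 to 2052904 in the 5-replicate experiment. The T cell table held normalized counts, from which 155088 to 1316341 reads per library were recovered. Each OVA library held more reads (423594, 614630 and 1316341) than each BSA library (271134, 155088 and 402391). Depth can therefore not be told apart from the particle in T cells. Levels are given as mean ± SD in CPM, counts scaled to a library total of 1e+06, or in normalized counts for T cells, and changes as log2 fold change ± SE. The labels do not say whether the replicates of a group came from separate animals, so the p-values measure the spread between samples.

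Transcripts from the Y chromosome marked 3 of the 5 non-immunized libraries (replicates 1 to 3), 2 of the 5 OVA libraries (replicates 3 and 4) and 0 of the 5 BSA libraries of the 5-replicate experiment. No library of the time course or the costimulation experiment reached the level of 20 CPM that marked a library, and all 6 T cell libraries did. Xist, which is expressed from the inactive X chromosome of females, stood at 87.5, 98.0 and 94.8 normalized counts in the T cells of the BSA group. In the OVA group it stood at 3.15, 2.02 and 50.0.

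**Figure D1:**
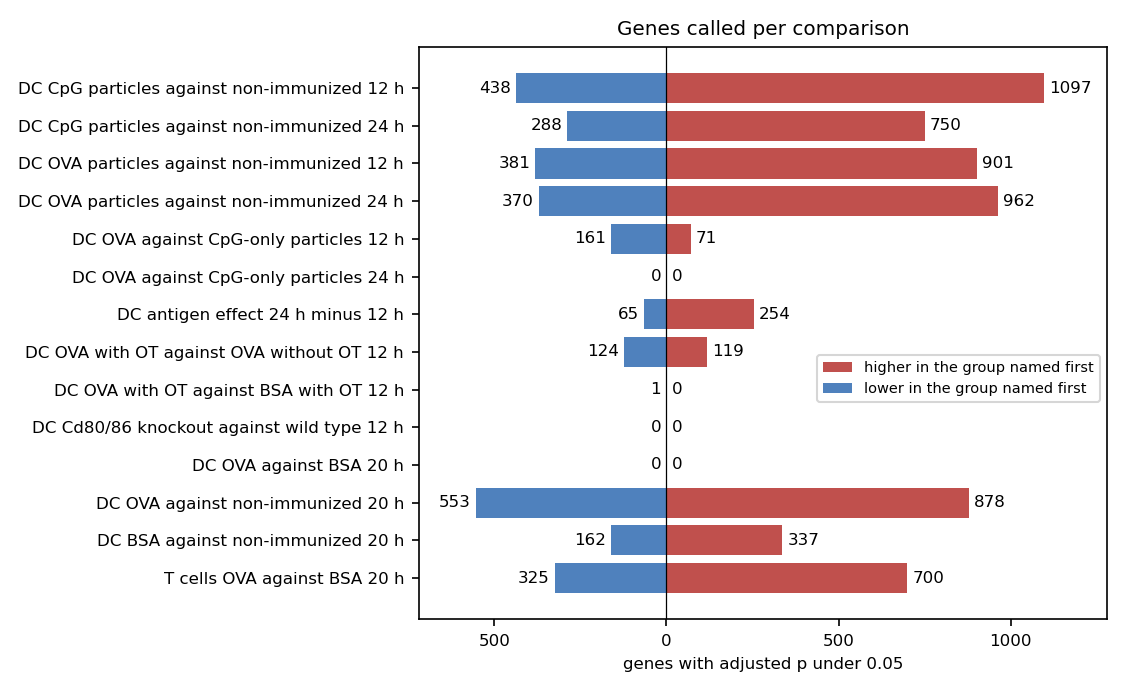
Number of genes called higher and lower (adjusted p under 0.05) in each of the 14 comparisons, by edgeR for DC and limma for T cells. The counts run from 0 in OVA against BSA at 20 h to 1535 in CpG-only particles against no immunization at 12 h.

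DC taken 12 h after CpG-only particles were compared with DC of non-immunized mice to record the response to adjuvant without antigen (2 libraries per group). All 33 measured type I interferon-stimulated genes rose, with a median log2 change of 2.35. Among them Cxcl10, a chemokine for activated T cells, stood at 2926 ± 47.0 against 163 ± 28.5 CPM. Rsad2, an antiviral enzyme, rose by a log2 of 3.55 ± 0.28. Of the interferon-gamma-induced genes 20 of 21 rose, Gbp2, a guanylate-binding protein, from 119 ± 7.64 to 596 ± 38.8 CPM. Genes of DC maturation and migration rose in 21 of 24 cases and fell in 2, and Langerhans cell and migratory DC markers rose with them in 7 of 8 (median 2.50; summed levels 2659 and 2952 against 567 and 370.1 CPM). The actin-bundling protein Fscn1 stood at 1028 ± 74.1 against 58.8 ± 38.0 CPM and the lymph node homing receptor Ccr7 at 865 ± 111 against 285 ± 41.4 CPM. Of the costimulatory and coinhibitory ligands 8 of 12 rose, including Cd40 (log2 2.80 ± 0.29) and Cd86 (log2 2.56 ± 0.39). NF-kB pathway genes rose in 15 of 20 cases, MHC class II genes in 12 of 17, MHC class I genes in 15 of 20, chemokines in 13 of 14 and cytokines in 7 of 10. The chemokine median of 3.45 became 3.16 with Ccl12, which had 0 counts in the controls, at its bound.

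Markers of other cell types moved in the same libraries. Neutrophil markers rose in 9 of 11 cases with a median of 6.75. The granule genes Camp and Ltf stood at 946 ± 211 and 600 ± 17.7 CPM, against 5.66 ± 3.49 and 2.33 ± 1.21 CPM without immunization. T cell markers fell in 18 of 21 cases (median -1.14), Lck, a T cell receptor kinase, from 582 ± 68.5 to 191 ± 2.33 CPM. B cell markers rose in 6 of 12 cases, monocyte and macrophage markers in 7 of 16 and type 1 conventional DC markers in 8 of 13. edgeR called 1535 of 9428 genes (1097 higher, 438 lower). Adjusted over the list alone, 33 type I interferon, 20 interferon-gamma, 21 maturation and 9 neutrophil genes were called higher, with 2 maturation genes and 18 T cell genes lower. Camera called the type I interferon (adjusted p = 2.77e-40), interferon-gamma (2.06e-19), maturation (1.34e-18), neutrophil (1.77e-08) and T cell marker (5.29e-16) lists. With an estimated correlation these calls were lost (adjusted p = 0.0773, 0.0773, 0.0903, 0.12 and 0.0773). DESeq2 called 1015 genes and the authors in their deposited table called 998. Without non-immunized replicate 1, non-immunized replicate 2 or CpG 12 h replicate 2 edgeR called 867, 714 or 828. In simulated data at this size the test recovered 37% of 2-fold and 82% of 4-fold changes.

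At 24 h after CpG-only particles the interferon genes were still high, with 32 of 33 type I genes (median 2.71) and 18 of 21 interferon-gamma-induced genes called higher than without immunization. Ifi44 rose from 9.62 ± 1.07 to 336 ± 127 CPM and Iigp1, an immunity-related GTPase, from 72.1 ± 1.76 to 919 ± 175 CPM. Maturation genes rose in 17 of 24 cases and costimulatory and coinhibitory ligands in 8 of 12, with 1 lower. Migratory DC markers rose in 6 of 8 cases (median 1.74; summed levels 2458 and 1669 against 567 and 370.1 CPM). Cd274, which encodes PD-L1, rose by a log2 of 2.27 ± 0.22 and Ccr7 by 1.70 ± 0.21. Immediate early genes rose in 8 of 18 cases, among them Jun (log2 3.08 ± 0.32). B cell markers rose in 11 of 12 cases (median 3.26), and Ms4a1, which encodes CD20, stood at 231 ± 216 against 18.4 ± 1.17 CPM with a wide spread between its 2 libraries. Monocyte and macrophage markers fell in 6 of 16 cases and rose in 3, with Lyz2 at 122 ± 88.5 against 608.3 ± 45.6 CPM and Csf1r at 46.9 ± 30.5 against 247 ± 60.6 CPM. Of the neutrophil markers 1 of 11 rose and 2 fell.

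edgeR called 1038 genes in that comparison (750 higher, 288 lower), DESeq2 704 and the authors in their deposited table called 709. With p adjusted within each list, 33 type I interferon, 20 interferon-gamma, 18 maturation and 11 B cell genes were higher, with 1 maturation gene and 1 B cell gene lower. Camera adjusted p-values for those lists were 1.3e-58, 2.66e-29, 6.92e-15 and 5e-06. The calls were lost with an estimated correlation (adjusted p = 0.0516, 0.0516, 0.199 and 0.299). Without non-immunized replicate 1 or 2 edgeR called 538 or 446 genes. Simulated changes of 2-fold and 4-fold were recovered in 32% and 93% of cases.

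OVA particles were compared with no immunization at the same times to record the response to antigen and adjuvant together. At 12 h all 33 type I interferon genes rose (median 2.97), with Cxcl10 at 6307 ± 1073 against 163 ± 28.5 CPM and Isg15, a ubiquitin-like protein, up by a log2 of 4.31 ± 0.28. Interferon-gamma-induced genes rose in 20 of 21 cases (median 2.38). Chemokines rose in 10 of 14 cases, including Ccl2 (log2 4.22 ± 0.42), and cytokines in 7 of 10, including Il1rn, the interleukin-1 receptor antagonist (log2 3.68 ± 0.37). Migratory DC markers rose in 4 of 8 cases (median 1.38). Maturation genes rose in 9 of 24 cases and fell in 1, with Fscn1 at 221 ± 53.9 CPM and Ccr7, which was not called, at 308 ± 2.51 CPM. Glycolysis genes rose in 6 of 15 cases, unfolded protein response genes in 7 of 16 and oxidative phosphorylation genes in 6 of 71. Gzmb, the cytotoxic protease granzyme B, stood at 132 ± 29.0 CPM against 1.11 ± 1.57 CPM, the latter from 3 counts. Neutrophil markers rose in 8 of 11 cases (median 3.37), monocyte and macrophage markers in 9 of 16, and T cell markers fell in 12 of 21.

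At 12 h edgeR called 1282 genes (901 higher, 381 lower), DESeq2 795 and the authors in their deposited table called 798. Without OVA 12 h replicate 1, Fscn1 was not called (log2 1.64, adjusted p = 0.0531, the highest over its alternatives, with 2.52e-15 the lowest). The counts were 622 without non-immunized replicate 1, 529 without non-immunized replicate 2, 584 without OVA 12 h replicate 1 and 831 without OVA 12 h replicate 2. Within single lists, 33 type I interferon, 20 interferon-gamma and 15 maturation genes were higher, 3 of the last list lower. Camera gave adjusted p-values of 1.99e-55, 4.55e-32 and 1.08e-04 for these lists, and adjusted p = 0.0569, 0.0513 and 0.346 with an estimated correlation. The simulated recovery was 37% at 2-fold and 85% at 4-fold.

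At 24 h after OVA particles the maturation genes rose in 21 of 24 cases (median 2.69). Ccr7 stood at 1632 ± 444 against 285 ± 41.4 CPM, Fscn1 at 1351 ± 243 against 58.8 ± 38.0 CPM, and Socs2, a suppressor of cytokine signalling, at 636 ± 176 against 52.3 ± 8.54 CPM. Il12b, the shared subunit of interleukin-12 and interleukin-23, rose by a log2 of 3.67 ± 0.71 and Il15 by 2.96 ± 0.34. Costimulatory and coinhibitory ligands rose in 9 of 12 cases (median 2.29) and NF-kB genes in 15 of 20, among them Relb (log2 2.32 ± 0.22). Type I interferon genes rose in 32 of 33 cases and interferon-gamma-induced genes in 18 of 21. Langerhans cell and migratory DC markers rose in 7 of 8 cases (median 2.65). Monocyte and macrophage markers fell in 7 of 16 cases and rose in 2, with Lyz2 at 94.1 ± 17.2 against 608.3 ± 45.6 CPM. T cell markers fell in 12 of 21 cases and neutrophil markers rose in 6 of 11 and fell in 1.

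That comparison had 1332 called genes by edgeR (962 higher, 370 lower), 887 by DESeq2 and 883 in the authors' deposited table. Without non-immunized replicate 1, non-immunized replicate 2 or OVA 24 h replicate 1 the count was 783, 641 or 667. When adjustment was limited to a list, 22 maturation, 11 costimulatory, 17 NF-kB and 32 type I interferon genes were higher, with 1 costimulatory gene lower. The camera adjusted p of the maturation list was 8.81e-26 and that of the migratory DC markers 2.18e-09 (adjusted p = 0.103 and 0.0915 with an estimated correlation). Of simulated changes 30% were recovered at 2-fold and 86% at 4-fold. The CpG-only and OVA responses share their controls. At 12 h they had 638 called genes higher in both and 217 lower in both, where independence gives 105 and 17.7. At 24 h the counts were 596 and 167, where independence gives 76.5 and 11.3. The covariance of the log2 changes was 0.648 at 12 h and 0.624 at 24 h, against 0.0597 and 0.06 for simulated groups without change.

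**Figure D2:**
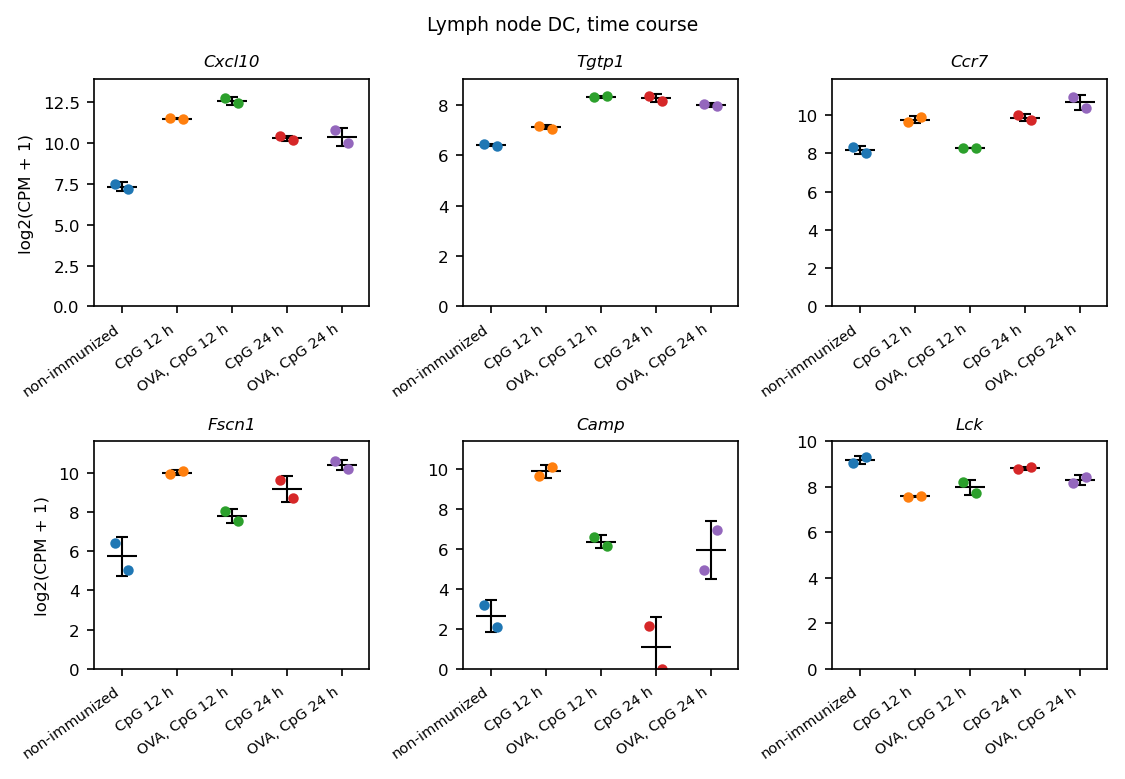
Level of Cxcl10, Tgtp1, Ccr7, Fscn1, Camp and Lck in each library of the time course, as log2(CPM + 1), with the mean and SD of each group. Ccr7 stands at 308 CPM in the OVA group at 12 h and at 1632 CPM at 24 h.

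The comparison of OVA with CpG-only particles addresses what antigen adds to the adjuvant response. At 12 h, 12 of 21 interferon-gamma-induced genes were higher with OVA and 0 were lower. Tgtp1, an interferon-gamma-induced GTPase, stood at 322 ± 9.11 against 138 ± 8.30 CPM and Serpina3g, a serine protease inhibitor, at 778 ± 11.6 against 341 ± 43.5 CPM. Type I interferon genes were higher in 10 of 33 cases, among them Cmpk2 (log2 1.10 ± 0.19) and Cxcl10 (log2 1.11 ± 0.23). Maturation genes fell in 15 of 24 cases (median -1.51). Ccr7 stood at 308 ± 2.51 against 865 ± 111 CPM, Fscn1 at 221 ± 53.9 against 1028 ± 74.1 CPM, and Relb, an NF-kB subunit, at 150 ± 21.2 against 358 ± 29.0 CPM. MHC class II genes fell in 3 of 17 cases, including H2-Eb1 (log2 -1.70 ± 0.33), and migratory DC markers in 4 of 8. Neutrophil markers fell in 5 of 11 cases in the same comparison (median -2.11), with Camp at 81.8 ± 18.0 against 946 ± 211 CPM. Type 1 conventional DC markers fell in 3 of 13 cases, including the transcription factor Batf3 at 57.8 ± 26.8 against 257 ± 63.7 CPM.

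At 12 h edgeR called 232 genes between the particles (71 higher, 161 lower with OVA), DESeq2 194 and the authors in their deposited table called 195. The count was 37 without CpG 12 h replicate 2, 51 without OVA 12 h replicate 1 and 24 without OVA 12 h replicate 2. Of 22 called genes followed under each setting, 19 kept their call without CpG 12 h replicate 1, 8 without CpG 12 h replicate 2, 13 without OVA 12 h replicate 1 and 6 without OVA 12 h replicate 2. Adjusted over the list alone, 17 interferon-gamma and 29 type I interferon genes were higher and 19 maturation and 6 neutrophil genes lower. Camera adjusted p-values were 8.28e-23, 3.07e-30, 8.75e-26 and 2.54e-09, against adjusted p = 0.139, 0.183, 0.183 and 0.218 with an estimated correlation. The cytokine and chemokine lists had positive medians (0.21 and 0.19) and negative means (-0.07 and -0.15). Simulated changes were recovered in 41% of cases at 2-fold and 82% at 4-fold.

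At 24 h maturation genes had a median log2 difference of 0.89 in favour of OVA, with 24 of 24 positive and 0 called over all genes. Ccr7 stood at 1632 ± 444 against 930 ± 114 CPM (adjusted p = 0.148) and Serpinb6b, a protease inhibitor, at 448 ± 75.1 against 197 ± 45.2 CPM (adjusted p = 0.107). Ccl22, a chemokine of mature DC, stood at 261 ± 49.4 against 95.5 ± 12.6 CPM (adjusted p = 0.148). Neutrophil markers had a median of 2.04 with 10 of 11 positive, and Camp, with 2 counts in the CpG-only group, had the smallest adjusted p of all genes, 0.0522. B cell markers had a median of -1.44 with 1 of 12 positive. The libraries of both groups overlapped in these cell types, with summed levels of 808 and 3294 CPM (CpG-only) and 683 and 1329 CPM (OVA) for B cell markers, and 909 and 106 against 493 and 2655 CPM for neutrophil markers. Migratory DC markers had a median of 0.90 with 7 of 8 positive and 0 called. edgeR called 0 genes, with 959 at an unadjusted p under 0.05. DESeq2 called 29 and the authors in their deposited table called 37 (34 higher, 3 lower). With p adjusted within each list, 21 maturation genes and 5 neutrophil genes were higher and 8 B cell genes lower. Camera called these 3 lists (adjusted p = 2.14e-25, 2.14e-05 and 8.62e-06), and none with an estimated correlation (adjusted p = 0.288, 0.452 and 0.459). Without CpG 24 h replicate 1 edgeR called 453 genes, without CpG 24 h replicate 2 it called 1 and without OVA 24 h replicate 1 it called 3. The test recovered 23% of simulated 2-fold and 90% of 4-fold changes.

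The difference between the antigen effects at 24 h and 12 h was tested as an interaction. It was positive for 19 of 24 maturation genes (median 2.39), among them Ccr7 (2.304 ± 0.30), Fscn1 (3.37 ± 0.47), Socs2 (2.49 ± 0.32) and Serpinb6b (3.13 ± 0.37), and for the NF-kB genes Relb (2.07 ± 0.30) and Traf1 (2.00 ± 0.29). Migratory DC markers moved with them, with 5 of 8 positive (median 2.36; camera adjusted p = 2.5e-09, adjusted p = 0.159 with an estimated correlation). Their summed levels were 2659 and 2952 (CpG-only) and 963 and 776 CPM (OVA) at 12 h, and 2458 and 1669 against 4607 and 3353 CPM at 24 h. It was negative for 10 of 21 interferon-gamma-induced genes, including Tgtp1 (-1.47 ± 0.25), and for 6 of 33 type I interferon genes. Neutrophil markers had a positive interaction in 6 of 11 cases (median 3.76), and T cell markers a negative one in 2 of 21. edgeR called 319 genes (254 positive, 65 negative), with 1407 at an unadjusted p under 0.05, and DESeq2 242. Within single lists, 21 maturation and 7 neutrophil genes were positive and 14 interferon-gamma genes negative. Camera adjusted p-values for these lists were 2.57e-32, 6.22e-08 and 1.73e-15, and adjusted p = 0.159, 0.279 and 0.159 with an estimated correlation. The count was 155 without CpG 12 h replicate 2, 744 without CpG 24 h replicate 1, 176 and 164 without OVA 12 h replicate 1 or 2, and 175 without OVA 24 h replicate 1. Simulated interactions were recovered in 8% of cases at 2-fold and 52% at 4-fold.

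The costimulation experiment asked what OT cells change in DC that received OVA (12 h, 2 libraries per group). Natural killer (NK) cell markers fell with OT cells in 12 of 13 cases, with a median of -4.64. Nkg7, a granule protein of cytotoxic cells, stood at 10.5 ± 12.9 CPM with OT cells and 641 ± 414 CPM without, and the receptor gene Klre1 at 3.69 ± 1.43 and 133 ± 83.4 CPM. T cell markers fell in 8 of 17 cases, Lck from 95.2 ± 30.2 to 5.14 ± 1.60 CPM. Ifng, which encodes interferon-gamma, stood at 23.5 and 0 CPM in the libraries with OT cells and at 687 and 2147 CPM in those without. Its log2 change was -6.72 ± 1.52 (adjusted p = 0.0454), and DESeq2 did not call it (adjusted p = 0.204, in a range over its alternatives from 1.98e-45 to 0.316). Fasl, the ligand of the death receptor Fas, had 0 counts with OT cells and was at least 34.7-fold lower than the 51.4 ± 21.9 CPM without them, with a floor of 3 counts over the group.

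In the same libraries 8 of 24 maturation genes were higher with OT cells and 1 was lower (median 1.31). Langerhans cell and migratory DC markers moved with them, with 7 of 10 positive and 1 called (median 1.21; summed levels 6716 and 5923 with OT cells, 1406 and 2448 CPM without; camera adjusted p = 0.00994, adjusted p = 0.576 with an estimated correlation). Fscn1 stood at 2916 ± 249 against 647 ± 317 CPM and Tmem176a, a membrane protein of DC, at 1210.0 ± 7.66 against 288 ± 86.6 CPM. Icosl, the ligand of the T cell costimulator ICOS, rose by a log2 of 1.74 ± 0.35, Batf3 by 1.65 ± 0.33 and Ltc4s, leukotriene C4 synthase, by 3.60 ± 0.45. Ccr7 stood at 1717 ± 463 against 582 ± 259 CPM (adjusted p = 0.181) and Cd83 at 348 ± 160 against 130.4 ± 59.2 CPM (adjusted p = 0.156). Ribosome biogenesis and MYC target genes fell in 2 of 24 cases (median -0.80), including Srm, spermidine synthase, at 32.1 ± 0.0199 against 101 ± 11.8 CPM. Plasmacytoid DC markers had a median of -2.45 with 0 called, and 1 of 4 B cell markers fell. edgeR called 243 genes (119 higher, 124 lower), DESeq2 329 and the authors in their deposited table called 479. When adjustment was limited to a list, 12 NK and 14 T cell genes were lower and 17 maturation genes higher, with 1 maturation gene lower and 1 T cell gene higher. Camera called the NK, T cell and maturation lists (adjusted p = 8.24e-13, 5.67e-09 and 5.88e-12), with adjusted p = 0.468 for each with an estimated correlation. The chemokine median (-0.30) and mean (-0.07) were negative where camera gave an upward direction.

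The count with and without OT cells was 136 without the first OVA library lacking OT cells, 12 without OVA with OT replicate 1 and 8 without OVA with OT replicate 2. Of 21 called genes followed under each setting, 15 kept their call without replicate 1 of the OVA group lacking OT cells and 19 without its replicate 2. Without OVA with OT replicate 1 or 2, 4 or 3 kept it. With only the libraries of these groups in the fit edgeR called 486 genes, and without a filter on low counts 917. The test recovered 5% of simulated 2-fold and 60% of 4-fold changes.

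**Figure D3:**
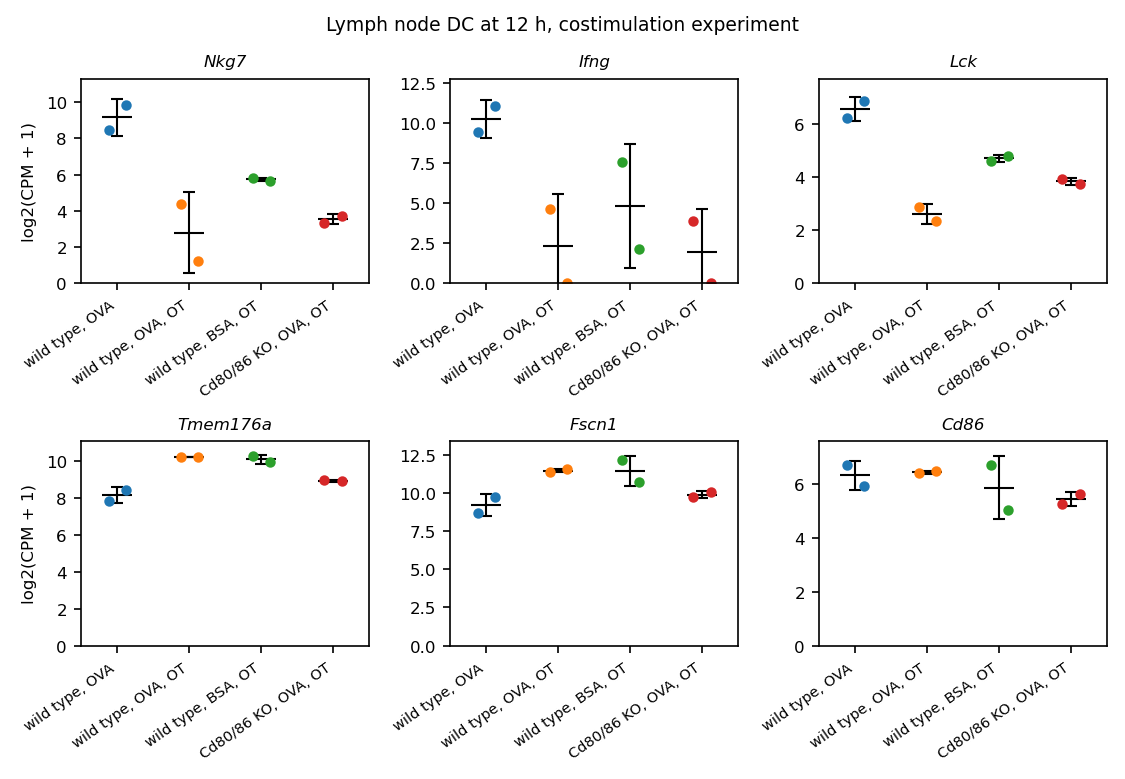
Level of Nkg7, Ifng, Lck, Tmem176a, Fscn1 and Cd86 in each library of the costimulation experiment, as log2(CPM + 1), with the mean and SD of each group. Nkg7 averages 641 CPM in the OVA group without OT cells and 10.5 CPM in the OVA group with them.

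With OT cells present, DC of mice given OVA were compared with DC of mice given BSA, which the OT receptors do not recognize. Ctse, an endosomal protease, was the 1 called gene and stood at 3.58 ± 0.621 with OVA against 68.5 ± 4.82 CPM with BSA (log2 -4.26 ± 0.40, adjusted p = 0.00422). It was not called without OVA with OT replicate 1 (adjusted p = 0.452) or replicate 2 (adjusted p = 0.143), and its lowest adjusted p over the alternatives was 2.06e-13. Type I interferon genes had a median of 0.54 with 31 of 33 positive and 0 called. Xaf1, an interferon-induced protein of cell death, stood at 215 ± 24.9 against 87.2 ± 27.8 CPM (adjusted p = 0.454). T cell markers had a median of -2.75, or -2.22 with the 4 genes that had 0 counts at their bound, and type 2 conventional DC markers one of -1.06. Plasmacytoid DC markers had a median of -2.42, and Siglech stood at 28.4 ± 17.5 against 386 ± 515 CPM, with a log2 of -3.72 that turned to 0.45 without BSA with OT replicate 3. Adjusted over the list alone, 11 T cell, 7 plasmacytoid and 6 type 2 conventional DC markers were lower and 0 type I interferon genes higher. BSA replicate 3 had the highest summed level of the 4 libraries in each of these 3 marker lists. Plasmacytoid DC markers summed to 1717 and 7954 CPM with BSA (replicates 1 and 3) and 2785 and 2373 CPM with OVA, T cell markers to 344 and 734 against 334 and 264 CPM, and type 2 conventional DC markers to 1373 and 2401 against 1273 and 1028 CPM. Camera called the type I interferon and T cell lists (adjusted p = 1.51e-08 and 1.25e-05; adjusted p = 0.733 and 0.697 with an estimated correlation).

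edgeR had 850 genes at an unadjusted p under 0.05 in OVA against BSA with OT cells. DESeq2 called 12 genes and the authors in their deposited table called 7, all lower with OVA. Without BSA with OT replicate 1 or 3 edgeR called 200 or 3, and without OVA with OT replicate 1 or 2 it called 0. With no filter on low counts it called 227, and with only the libraries of these groups 4. Simulated changes were recovered in 1% of cases at 2-fold and 64% at 4-fold. This comparison and that with and without OT cells share their OVA libraries. They had 0 called genes higher in both and 1 lower in both, Ctse, with a covariance of log2 changes of 0.383 against 0.120 for simulated groups without change. The correlation was 0.550 against 0.502 and the share of genes with the same sign 61.6% against 66.9%, so by these measures the comparisons were close to or below the simulated groups.

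The knockout asked what the costimulatory ligands CD80 and CD86, which bind CD28 on T cells, contribute. Cd86 stood at 42.9 ± 7.49 CPM in the knockout and 86.1 ± 3.13 CPM in the wild type (log2 -1.01 ± 0.47, adjusted p = 0.442). Cd80 stood at 8.31 ± 5.73 against 11.2 ± 0.746 CPM (log2 -0.54 ± 0.75, adjusted p = 0.804), and at 0.13 on the log2 scale without knockout replicate 1. A targeted gene can still give reads outside the removed part, so the tables cannot check the genotype. Maturation genes had a median of -0.89 with 1 of 24 positive. Migratory DC markers moved with them (median -0.90, 3 of 10 positive; summed levels 2569 and 3130 against 6716 and 5923 CPM), and monocyte and macrophage markers moved the other way (median 0.56, 14 of 18 positive; 15970 and 12344 against 8412 and 8713 CPM). Camera gave these lists adjusted p = 0.0355 and 0.0157, and adjusted p = 0.597 and 0.623 with an estimated correlation. Fscn1 stood at 969.8 ± 154 against 2916 ± 249 CPM (adjusted p = 0.294) and Tmem176a at 487 ± 15.3 against 1210.0 ± 7.66 CPM (adjusted p = 0.222). Plasmacytoid DC markers had a median of 2.41, with Siglech at 389.7 ± 6.84 against 28.4 ± 17.5 CPM (adjusted p = 0.286). Il1b, which encodes interleukin-1 beta, stood at 885 ± 112 against 248 ± 13.1 CPM (adjusted p = 0.283). T cell markers had a median of 1.85, or 0.92 with the 4 genes that had 0 counts in the wild type at their bound.

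edgeR called 0 genes in the knockout comparison, with 1068 at an unadjusted p under 0.05 and a smallest adjusted p of 0.121. DESeq2 called 48 and the authors in their deposited table called 24, which in that table are 2 higher and 22 lower in the knockout. With only the libraries of these groups in the fit edgeR called 679 genes, among them Fscn1, Cd86 and Tmem176a, and without a filter on low counts 303. Replicates had a chi-square per gene of 3.98 in the knockout and 4.01 in the wild type with OVA and OT cells. In the groups outside this comparison, which share the estimate of the spread, it was 11.07 (BSA with OT) and 14.9 (OVA without OT). Whether this accounts for the 0 calls was not tested, and they do not show that the knockout had no effect. With p adjusted within each list, 4 maturation genes were lower and 2 plasmacytoid genes higher. Camera called both lists (adjusted p = 2.34e-08 and 7.17e-05), with adjusted p = 0.597 for each with an estimated correlation. In simulated data 4% of 2-fold and 78% of 4-fold changes were recovered.

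OVA particles were compared with no immunization at 20 h in 5 libraries per group. Type I interferon genes rose in 32 of 33 cases (median 2.82). Isg15 stood at 1263 ± 302 against 76.9 ± 30.6 CPM, Irf7, the transcription factor that amplifies type I interferon production, at 588 ± 228 against 31.9 ± 20.1 CPM, and Oas3, a sensor of double-stranded RNA, at 154 ± 65.4 against 6.03 ± 3.59 CPM. Interferon-gamma-induced genes rose in 18 of 19 cases, including Igtp (log2 3.21 ± 0.38) and Gbp2 (log2 2.09 ± 0.24). MHC class I genes rose in 12 of 20 cases, with H2-D1 at 7996 ± 653 against 4813 ± 353 CPM. Maturation genes rose in 11 of 24 cases and fell in 1, Ccr7 to 3692 ± 655 from 1512 ± 188 CPM and Fscn1 to 7229 ± 1924 from 3218 ± 624 CPM. Of the costimulatory and coinhibitory ligands 6 of 12 rose, including Cd200 (log2 2.03 ± 0.27) and Cd40 (log2 0.75 ± 0.17). Cd86 stood at 125 ± 34.4 against 94.9 ± 21.3 CPM (adjusted p = 0.166) and was called without non-immunized replicate 3 and OVA replicate 3 (log2 0.58, adjusted p = 0.0374, with 0.406 the highest over its alternatives), a setting chosen after seeing the data.

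Monocyte and macrophage markers fell in 9 of 12 cases with OVA (median -1.82), Lyz2 to 42.2 ± 19.4 from 425 ± 202 CPM and the chemokine receptor Ccr2 to 10.2 ± 5.55 from 151 ± 96.6 CPM. Type 2 conventional DC markers fell in 7 of 12 cases and rose in 1 (median -1.15), with the lectin Cd209a at 4.34 ± 5.53 against 109 ± 126 CPM and Sirpa at 66.8 ± 21.8 against 139 ± 5.41 CPM. Type 1 conventional DC markers fell in 5 of 11 cases and rose in 2, and migratory DC markers rose in 5 of 10. OVA replicate 3 stood apart from its group, with a chi-square per gene of 11.02 to 15.1 against the other OVA libraries, which had 3.26 to 6.49 among themselves, and an Rn45s share of 0.0364% against 0.633% to 1.35%. It had the lowest monocyte sum (191 CPM, the others 315 to 658) and the highest migratory DC sum (20018 CPM, the others 12944 to 15871) of the group. Without it the log2 change of Lyz2 was -3.14 and that of Ccr2 -3.61, and edgeR called 1199 genes. It also had the highest total (2052904 counts), and chi-square per gene grows with depth. Non-immunized replicate 3 had the lowest total (367209 counts) and the lowest correlations with its group (0.893 to 0.900). Its monocyte sum was 3130 CPM, which raises the level that these markers fell from. Non-immunized replicates 1 and 2, also marked by Y-linked transcripts, had 1822 and 1464 CPM, and the unmarked replicates 4 and 5 had 895 and 1019 CPM. Without non-immunized replicate 3 edgeR called 1292 genes. The hormone gene Sct and Apod, an apolipoprotein, were among the largest rises, from 1.59 ± 0.935 to 50.4 ± 28.7 CPM and from 1.78 ± 2.14 to 29.9 ± 5.82 CPM. edgeR called 1431 of 9159 genes (878 higher, 553 lower), DESeq2 1483 and the authors in their deposited table called 1537. Within single lists, 32 type I interferon, 18 interferon-gamma, 12 MHC class I, 17 maturation and 5 migratory DC genes were higher, with 1 maturation gene lower, and 9 monocyte and 7 type 2 conventional DC genes were lower. Camera adjusted p-values for the type I interferon, interferon-gamma, maturation and monocyte lists were 4.62e-30, 5.83e-16, 3.41e-08 and 5.18e-08. With an estimated correlation these became adjusted p = 0.065, 0.065, 0.0611 and 0.0912. The NF-kB (adjusted p = 0.0474), MHC class I (adjusted p = 0.0447) and migratory DC (adjusted p = 0.0447) lists kept their calls with it. The test recovered 70% of simulated 2-fold and 99% of 4-fold changes.

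BSA particles, which lack OVA, were compared with no immunization at 20 h to record the response without that antigen. Type I interferon genes rose in 27 of 33 cases (median 2.04) and interferon-gamma-induced genes in 9 of 19. Isg15 stood at 806 ± 669 and Irf7 at 333 ± 280 CPM, against 76.9 ± 30.6 and 31.9 ± 20.1 CPM, and Gbp2 rose by a log2 of 1.13 ± 0.24. Maturation genes rose in 8 of 24 cases, including Ccr7 (log2 0.87 ± 0.19), and MHC class I genes in 7 of 20, including the immunoproteasome subunit Psmb8 (log2 0.70 ± 0.12). Migratory DC markers summed to 7259, 6968 and 7696 CPM in non-immunized replicates 1 to 3, which were marked by Y-linked transcripts. In non-immunized replicates 4 and 5, which were not marked, they summed to 10948 and 10215 CPM. With BSA, where 0 of the 5 libraries were marked, they summed to 17668 CPM in replicate 1 and to 10387 to 13636 CPM in the others. The rise of this list is therefore not separated from what the Y-linked transcripts mark. BSA replicate 1 had a chi-square per gene of 5.63 to 9.69 against the other BSA libraries, which had 2.64 to 4.69 among themselves. Monocyte and macrophage markers fell in 9 of 12 cases (median -1.67), Lyz2 to 75.1 ± 36.9 CPM and Csf1r to 34.4 ± 9.52 from 172 ± 97.6 CPM. They summed to 1822, 1464 and 3130 CPM in the marked non-immunized libraries and to 895 and 1019 CPM in replicates 4 and 5. With BSA the sums ran from 380 to 568 CPM, so the fall was smaller against the unmarked controls. Type 2 conventional DC markers fell in 4 of 12 cases and rose in 1. edgeR called 499 genes (337 higher, 162 lower), DESeq2 619 and the authors in their deposited table called 654. With a term for Y-linked transcripts, an alternative chosen after seeing the data, it called 187. Without non-immunized replicate 1 or 2 it called 224 or 295, and without BSA replicate 1, 3 or 5 it called 205, 306 or 276. When adjustment was limited to a list, 31 type I interferon, 15 interferon-gamma, 14 maturation and 9 MHC class I genes were higher and 9 monocyte genes lower. Camera called the type I interferon (adjusted p = 1.18e-23), interferon-gamma (8.5e-09), maturation (8.5e-09) and monocyte (9.85e-10) lists, with adjusted p = 0.118, 0.22, 0.0835 and 0.1 with an estimated correlation. The MHC class I (adjusted p = 0.0386) and migratory DC lists (adjusted p = 0.0232) kept their calls with it. Simulated 2-fold and 4-fold changes were recovered in 71% and 96% of cases.

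The OVA and BSA responses at 20 h share their controls and had 317 called genes higher in both and 140 lower in both, where independence gives 32.3 and 9.78 and simulated groups without change gave 0. With the non-immunized libraries split between the comparisons the medians over 20 splits were 60.5 and 37.5, with ranges of 3 to 93 and 3 to 77. For these splits independence gives medians of 3.45 and 1.37, since each comparison then held fewer controls and called fewer genes. The covariance of log2 changes was 0.239 against 0.0333 in the simulated groups.

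The comparison of OVA with BSA particles at 20 h asked for the part of the DC response that depends on the antigen. All 33 type I interferon genes had positive log2 differences (median 0.77), as had all 19 interferon-gamma-induced genes (median 0.89). With all libraries edgeR called 0 of them over all genes. Igtp stood at 188 ± 72.5 with OVA and 71.4 ± 44.9 CPM with BSA (log2 1.40 ± 0.33, adjusted p = 0.527) and Gbp2 at 670 ± 233 and 345 ± 99.0 CPM (log2 0.96 ± 0.23, adjusted p = 0.527). Without OVA replicate 5, Igtp and Gbp2 were called (log2 1.61 and 1.13, adjusted p = 0.0399 for both, with 1.000 the highest over the alternatives). Cd274 stood at 194 ± 46.7 against 113 ± 27.8 CPM (adjusted p = 0.527). The maturation list had a median of 0.11 with 15 of 24 positive, and Ccr7 stood at 3692 ± 655 against 2756 ± 1007 CPM (adjusted p = 0.766). Cholesterol synthesis genes had a median of -0.27 with 2 of 18 positive and oxidative phosphorylation genes one of -0.12 with 10 of 71 positive. Monocyte and macrophage markers had a median of -0.30.

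edgeR called 0 of 9159 genes between OVA and BSA, with 561 at an unadjusted p under 0.05 where 458 fall by chance. DESeq2 called 0, and the authors' deposited table called 6 higher, which were Wars, Igtp, Parp9, Sp110, Cd274 and Gbp2 and of which the 3 absent from the rule for named genes are given because the count is small. Without OVA replicate 5 edgeR called 4. Adjusted over the list alone, 16 type I interferon and 14 interferon-gamma genes were higher and 0 maturation genes. Camera called both interferon lists (adjusted p = 4.1e-27 and 2.94e-19), with adjusted p = 0.101 for each with an estimated correlation, and the cholesterol and oxidative phosphorylation lists (adjusted p = 2.22e-04 and 4.33e-06; adjusted p = 0.101 and 0.309 with an estimated correlation). Each library was also given a list score, the mean centred log2 level of its genes, in a test chosen after seeing the data. The interferon-gamma score was 0.83 ± 0.59 with OVA and 0.02 ± 0.48 with BSA (difference 0.81, two-sided exact permutation p = 0.0397 over 252 arrangements, 0.119 adjusted by Benjamini-Hochberg over 3 lists). For the type I score the difference was 0.90 (exact permutation p = 0.0873, adjusted 0.131), and for the maturation score 0.10 (exact permutation p = 0.198, adjusted 0.198). Simulated changes were recovered in 75% of cases at 2-fold and 97% at 4-fold. The simulated genes were drawn at random and varied independently, so these shares need not hold for the interferon genes.

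**Figure D4:**
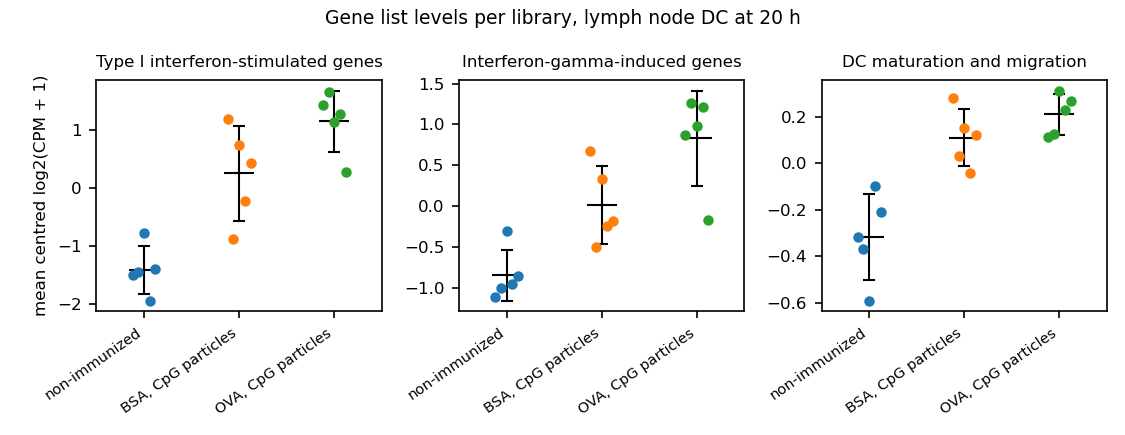
Level of gene lists in each of the 15 libraries of the 5-replicate experiment, with the mean and SD of each group. The interferon-gamma score averages 0.83 with OVA and 0.02 with BSA.

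OT-II T cells, which recognize an OVA peptide on MHC class II, were compared after OVA and BSA particles at 20 h (3 libraries per group) to record their activation. T cell activation genes rose in 15 of 19 cases with OVA (median 1.80). Il2, the T cell growth factor, stood at 128 ± 31.0 against 8.98 ± 2.53 normalized counts, its receptor chain Il2ra at 76.3 ± 17.4 against 15.7 ± 7.10 and Nr4a1, an early target of T cell receptor signals, at 348 ± 132 against 59.0 ± 20.1. Ribosome biogenesis and MYC target genes rose in 22 of 24 cases (median 1.56), with Srm at 342 ± 118 against 57.5 ± 6.95, and Myc itself rose by a log2 of 2.22 ± 0.28. Glycolysis genes rose in 4 of 12 cases, including Ldha, lactate dehydrogenase, at 608.1 ± 175 against 205 ± 22.0, oxidative phosphorylation genes in 18 of 71 and cell cycle genes in 6 of 8, including Mcm5 (log2 1.75 ± 0.28). Genes of naive and quiescent T cells fell in 10 of 22 cases (median -0.87). Txnip, which restrains glucose uptake, stood at 70.3 ± 20.53 against 179 ± 34.7 and S1pr1, the receptor for exit from lymph nodes, at 34.2 ± 15.8 against 91.1 ± 17.4. Tbx21, the transcription factor of T helper 1 cells, stood at 20.1 ± 10.97 against 2.55 ± 0.472 and was the 1 called gene of 6 in its list. DESeq2 gave it no adjusted p (log2 2.96), and with any OVA replicate left out it did not pass the filter and had no value. Cd69 rose by a log2 of 1.11 ± 0.27 and was not called without OVA replicate 1 (log2 0.85, adjusted p = 0.0615) or BSA replicate 3 (log2 0.90, adjusted p = 0.0824), with 0.00425 the lowest over its alternatives. S1pr1 was not called without BSA replicate 3 (log2 -1.42, adjusted p = 0.0582), with 0.00213 the lowest.

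Markers of 3 other cell types were lower with OVA without a called member. Conventional DC markers had a median of -1.03, B cell markers of -1.18 and plasmacytoid DC markers of -0.90, and H2-Aa, an MHC class II gene, stood at 440.0 ± 317 against 831 ± 113 (adjusted p = 0.0945). OVA replicate 1 had the lowest summed level of the 6 libraries in each of these 3 lists. B cell markers summed to 88.2, 979 and 489 with OVA and 1059, 628 and 840 with BSA, conventional DC markers to 595, 3302 and 2145 against 3947, 2945 and 3274, and plasmacytoid DC markers to 99.7, 786 and 344 against 607, 320.4 and 610.4. Type I interferon genes had a median of -0.55 with 6 of 32 positive and 1 called lower. Xist fell by 3.45 on the log2 scale, from 87.5, 98.0 and 94.8 normalized counts with BSA to 3.15, 2.02 and 50.0 with OVA. No term for Xist or Y-linked transcripts was fitted in T cells, so the called genes were not separated from this difference. Each BSA library held fewer recovered reads than each OVA library, while the totals in the file headers overlapped. limma called 1025 of 6452 genes (700 higher, 325 lower), DESeq2 on the recovered reads 821 and the authors in their deposited table called 793. Without OVA replicate 1, OVA replicate 3 or BSA replicate 3 the count was 369, 412 or 467. With p adjusted within each list, 18 activation, 23 ribosome biogenesis, 7 glycolysis, 23 oxidative phosphorylation and 7 cell cycle genes were higher and 18 naive T cell genes lower. Camera called the activation (adjusted p = 5.16e-12), ribosome (1.08e-16), naive (8.03e-09), glycolysis (0.00136), cell cycle (9.85e-04), oxidative phosphorylation (1.2e-07) and type I interferon (9.85e-04) lists. With an estimated correlation the first 5 had adjusted p = 0.278 and the last 2 adjusted p = 0.595. The conventional DC, B cell and plasmacytoid marker lists (adjusted p = 0.0106, 0.00404 and 0.0256) had adjusted p = 0.595 with it. In simulated data limma recovered 25% of 2-fold and 81% of 4-fold changes.

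**Figure D5:**
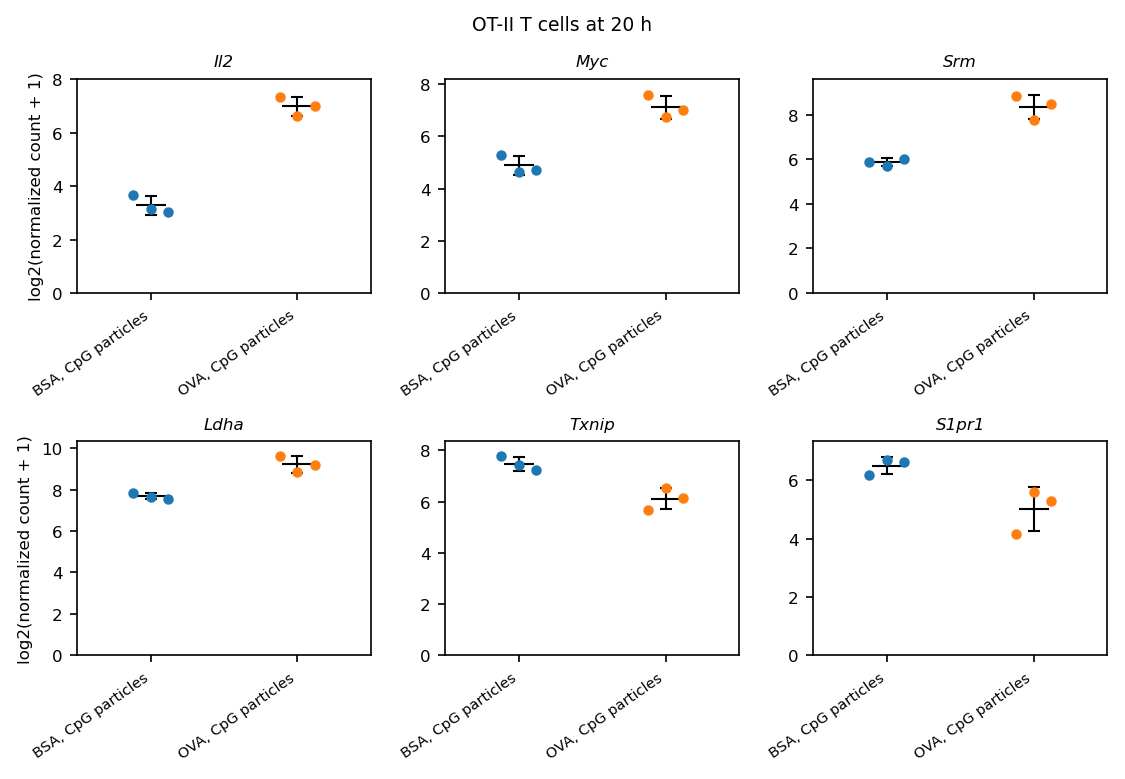
Level of Il2, Myc, Srm, Ldha, Txnip and S1pr1 in each OT-II T cell library, as log2(normalized count + 1), with the mean and SD of each group. Il2 averages 128 normalized counts with OVA and 8.98 with BSA.

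In DC, cell cycle genes rose in 5 of 20 cases at 12 h after CpG-only particles and in 7 of 20 after OVA particles, and ribosome biogenesis genes fell in 3 of 24 cases 24 h after OVA particles. Cholesterol synthesis genes had 1 of 17 members called at 12 h after CpG-only particles and 2 of 17 at 24 h after OVA particles, all higher. NK cell markers moved both ways in the time course, with 4 of 8 higher and 4 lower at 12 h after CpG-only particles, and rose in 4 of 6 cases with OVA at 20 h. Stromal and endothelial markers had 1 measured member in the time course, uncalled, and 1 of 3 higher with OT cells. In T cells 1 of 10 follicular helper genes, 1 of 7 regulatory T cell genes, 1 of 6 CD8 T cell markers, 1 of 6 NK cell markers and 2 of 14 unfolded protein response genes rose. Immediate early genes rose in 3 of 13 cases there and fell in 1, and no cholesterol synthesis gene (6 measured) or monocyte marker (9 measured) was called by limma. The 3 neutrophil markers in the T cell table did not pass the filter, with summed levels from 9.26 to 45.9 normalized counts per library, and the 1 stromal marker had a log2 change of -1.08.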

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

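The tests on single libraries, on library size and on other splits were chosen before their results were seen. So was the test on the sex of the mice, but its term for Y-linked transcripts was added after seeing the data. Those on NK cells, on the share of DC, on neutrophil RNA, on mature DC and on the list score were chosen only after. Of 102 tests for a single library far from the other 4 of its group at 20 h, 6 passed the 95% critical value of 0.71. Chance flags about 1 in 20 groups. Cd83 in BSA replicate 1 stood at 782 CPM, against 497 to 547 in the other libraries, and Zfp36 in the same library at 645 against 341 to 386. Cd86 in non-immunized replicate 5 stood at 59.2 CPM against 94.7 to 113. Igtp in OVA replicate 5 stood at 68.2 CPM against 179 to 258, and Mgl2 in OVA replicate 1 at 13.9 against 4.22 to 5.90. BSA replicate 3 had a total of 1.75 times 1e+06 counts against 1.20 to 1.32 in the same unit.

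For 14 named genes the effect of OVA over CpG-only particles differed between 24 h and 12 h by the test of the interaction. The log2 difference was 9.52 for Camp and 7.72 for Ngp, and Camp had 2 counts in the CpG-only group at 24 h. It was 3.13 for Serpinb6b, 2.98 for Anxa3, 2.49 for Socs2, 2.304 for Ccr7, 3.37 for Fscn1, 2.00 for Traf1, 2.07 for Relb and 2.18 for Cd83. The negative values were -1.47 for Tgtp1, -1.54 for Iigp1, -1.24 for Parp14 and -1.89 for Ifit1bl1. Parp14 was not called without CpG 12 h replicate 2 or without OVA 12 h replicate 1.

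Interferon-gamma-induced genes had a median log2 difference of 0.89 in favour of OVA over BSA particles in DC at 20 h, but edgeR and DESeq2 called 0 genes (561 at an unadjusted p under 0.05 by edgeR), the camera call was lost with an estimated correlation (adjusted p = 0.101), and the list score did not pass (exact permutation p = 0.0397, 0.119 adjusted over 3 lists). With a term for Y-linked transcripts the median was 0.765 (spread 0.119), which argues against the sex of the mice as the whole cause. The spread of list medians, here and below, comes from 1000 redraws of the list members (SD). It does not measure the variation between libraries, so what rests on it holds for these libraries only. Without each of the 10 libraries in turn the median ran from 0.740 (spread 0.114, without BSA replicate 2) to 1.04 (without BSA replicate 1). This argues against a single library. Library size stays open: its Spearman correlation with the list level was 0.0303 (permutation p = 0.945), within a spread of 0.333. That spread is the SD of a rank correlation over 10 libraries with no relation. A response to T cells that recognize OVA may account for the pattern and was not tested by itself.

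NK and T cell genes were higher in DC of mice without OT cells at 12 h. One explanation is a lower share of DC with every other cell type raised alike. The neutrophil median lay 3.38 above the NK median (spread 0.6247; -1.25 and -4.64), which argues against an equal rise only. Neutrophil markers summed to 4818 and 21037 CPM in the libraries without OT cells, so this yardstick varied between them. A lower share of DC with unequal rises of other cell types was not tested and stays open. RNA of NK cells in the sorted DC may be the source: 12 of 13 NK markers were called lower with OT cells, by log2 values from -1.69 to -6.31, and Nkg7 stood at 641 CPM without OT cells. The labels name negative selection and sorting, which would remove such cells, and non-immunized DC of the time course held 495 CPM of Nkg7. The tables cannot tell this apart from a change in cells of the DC gate, and the biological explanation, the presence of OT cells, stays open.

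Mature DC genes were lower with OVA than with CpG-only particles at 12 h, with a median of -1.51 (spread 0.196). Neutrophil markers fell too (median -2.11), so more neutrophil RNA in the CpG-only libraries would have raised, not lowered, the maturation genes with OVA, which argues against dilution as the cause. Fewer migratory or mature DC in the OVA libraries could lower the list and stays open, since the costimulatory median (-0.44) lay 1.064 above the maturation median with a spread of 0.388. The biological explanation, an effect of antigen on maturation, was not tested apart from it.

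Other splits of the same libraries were fitted for comparisons with at least 3 libraries per group. In OVA against no immunization at 20 h 1 of 100 splits, the real one, called as many as 1431 genes. The highest other called 4, so a chance split of these libraries is unlikely. In BSA against no immunization 1 of 100 called as many as 499, and the highest other called 81, so it is unlikely there too. The splits cannot separate immunization from other differences between the groups. Y-linked transcripts marked 3 of the 5 non-immunized and 0 of the 5 BSA libraries. With a term for them BSA against no immunization called 187 genes. In OVA against BSA the real split called 0 genes, so each of the 100 splits calls as many by construction and they say nothing on chance. The highest other called 18, with OVA replicates 1 to 4 and BSA replicate 3 on the same side, which may point to a structure of the samples that was not tested. For T cells the real split called 1025 and the highest of the other splits 0, and 10 splits are too few for a share under 0.05.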

How the results depend on the processing

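The term for Y-linked transcripts, the omission of non-immunized and OVA replicates 3 together, and for T cells edgeR and other pseudocounts were chosen after seeing the data. Of the counts 117 kept within 1.5 times their value over the alternatives and 76 moved. Of the single-gene values 2633 kept direction and side of the threshold, 152 fell below it, 60 passed it and 2 reversed. Siglech in OVA against BSA with OT cells turned from -3.72 to 0.45 without BSA replicate 3 and was -4.59 without BSA replicate 1. Cd80 in the knockout turned from -0.54 to 0.13 without knockout replicate 1 and was -1.38 without knockout replicate 2. With DESeq2 the counts were 1015 (CpG-only 12 h) and 795 and 887 (OVA 12 h and 24 h against no immunization), 29 (OVA against CpG-only 24 h), 12 (OVA against BSA with OT cells) and 48 (knockout). With no filter on low counts they were 469 and 240 (OVA against CpG-only 12 h and 24 h), 594 (interaction), 917 (with against without OT cells), 227 (OVA against BSA with OT cells), 303 (knockout) and 2 (OVA against BSA 20 h). With a mean of at least 1 CPM they were 8 (OVA against CpG-only 24 h) and 1 (knockout). With only the libraries of the groups compared they were 486 (with against without OT cells), 4 (OVA against BSA with OT cells) and 679 (knockout). With the replicate number as a block they were 696 (with against without OT cells) and 48 (knockout). With the term for Y-linked transcripts BSA against no immunization called 187. The cause was not tested in any of these.

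Same-numbered libraries correlated over 0.1 in 3 of 9 pairs of the costimulation experiment, 4 of 15 of the 5-replicate experiment, 2 of 20 of the time course and 0 of 3 of T cells, so libraries were not treated as paired. Between groups of 2 libraries both pairs have the same correlation by construction. In the time course both pairs over 0.1 thus had the value 0.148, and in the costimulation experiment 2 had the value 0.176. No paired analysis was possible because the groups share only replicate number 1, for OVA against BSA with OT cells. With an estimated correlation camera called 0 lists in every comparison except 3 in OVA and 2 in BSA against no immunization at 20 h. Against no immunization fry called 21 and 9 of 25 lists at 12 h and 24 h after CpG-only particles, and 15 and 13 after OVA particles. For OVA against CpG-only it called 1 of 25 at 12 h, 0 at 24 h and 3 for the interaction. It called 0 in each costimulation comparison and in OVA against BSA at 20 h. At 20 h it called 11 of 23 for OVA and 7 of 23 for BSA against no immunization, and 7 of 19 in T cells. With the non-immunized libraries split between the comparisons the overlap was 60.5 higher and 37.5 lower, where independence gives 3.45 and 1.37. Carry-over sets from OVA against BSA at 20 h were empty and gave no value.

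Leaving out 1 library in turn, with a lone library assumed to vary like the other groups, gave these lowest and highest counts. CpG-only against no immunization ran from 714 to 1099 at 12 h (non-immunized replicate 1 867, replicate 2 714, CpG 12 h replicate 2 828) and from 446 to 1126 at 24 h (non-immunized replicate 1 538, replicate 2 446). OVA ran from 529 to 831 at 12 h (non-immunized replicate 1 622, replicate 2 529, OVA 12 h replicate 1 584, replicate 2 831) and from 641 to 1054 at 24 h (non-immunized replicate 1 783, replicate 2 641, OVA 24 h replicate 1 667). OVA against CpG-only ran from 24 to 168 at 12 h (CpG 12 h replicate 2 37, OVA 12 h replicate 1 51, replicate 2 24) and from 0 to 453 at 24 h (CpG 24 h replicate 1 453, replicate 2 1, OVA 24 h replicate 1 3). The interaction ran from 155 to 744 (CpG 12 h replicate 2 155, CpG 24 h replicate 1 744, OVA 12 h replicate 1 176, replicate 2 164, OVA 24 h replicate 1 175). With against without OT cells ran from 8 to 321 (OVA without OT replicate 1 136, OVA with OT replicate 1 12, replicate 2 8), OVA against BSA with OT cells from 0 to 200 (BSA replicate 1 200, replicate 3 3, both OVA replicates 0) and the knockout from 0 to 0. At 20 h OVA against BSA ran from 0 to 4 (OVA replicate 5 4), OVA against no immunization from 994 to 1415 and BSA against no immunization from 205 to 494 (non-immunized replicate 1 224, replicate 2 295, BSA replicate 1 205, replicate 3 306, replicate 5 276). T cells ran from 369 to 1467 (OVA replicate 1 369, OVA replicate 3 412, BSA replicate 3 467). In the costimulation experiment, simulated 2-fold changes were recovered by edgeR in 5% (with against without OT cells), 1% (OVA against BSA) and 4% (knockout) of cases.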

Other observations

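All tests in this part were chosen after the results they follow were seen, except the sets planned from OVA against BSA at 20 h.

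The response to antigen was also followed from experiment to experiment. The sets planned for this, from OVA against BSA at 20 h, held 0 genes, so sets from other comparisons were used after seeing the data. The sorted cells differed between experiments even without immunization. T cell markers summed to 7419 and 7508 CPM in non-immunized libraries of the time course and to 365 to 516 CPM in those of the 5-replicate experiment. Migratory DC markers summed to 567 and 370 CPM and to 6968 to 10948 CPM. The tests of the sets did not take this into account. Genes called higher with OVA than with CpG-only particles at 12 h were positive in 51 of 56 cases in OVA against BSA at 20 h (camera adjusted p = 7.37e-23, adjusted p = 0.109 with an estimated correlation; fry adjusted p = 0.0962). The genes called lower were positive in 90 of 153 cases there (median 0.04, adjusted p = 0.740 with an estimated correlation). With against without OT cells, 7 of 66 of the higher set were positive (median -0.71, fry adjusted p = 0.218), the opposite direction. In OVA against BSA with OT cells 49 of 66 of the higher and 127 of 161 of the lower set were positive (adjusted p = 0.477 and 0.554 with an estimated correlation), in a comparison that shares its OVA libraries with the former. Genes called lower at 12 h, which include 15 of the 24 maturation genes, were positive in 154 of 161 cases with against without OT cells (adjusted p = 0.183 with an estimated correlation; fry adjusted p = 0.0812). In the knockout 56 of 66 of the higher and 3 of 161 of the lower set were positive (adjusted p = 0.383 and 0.236 with an estimated correlation). That comparison holds the same OVA libraries with the opposite sign, which alone pushes the signs apart, and no value without change was simulated for it. Genes called higher with OT cells were positive in 4 of 109 cases in OVA against CpG-only particles at 12 h (adjusted p = 0.0482 with an estimated correlation; fry adjusted p = 0.0178). At 24 h 104 of 109 were positive (adjusted p = 0.0536 with an estimated correlation; fry adjusted p = 0.0281). Genes called lower with OT cells were positive in 75 of 94 cases at 12 h (median 0.43, adjusted p = 0.0482 with an estimated correlation) and in 33 of 94 at 24 h (median -0.18, fry adjusted p = 0.297). With sets of adjusted p under 0.01 and a log2 change over 1 these calls were lost: the higher set was positive in 0 of 7 cases at 12 h and 7 of 7 at 24 h, and the lower set in 15 of 17 at 12 h (fry adjusted p = 0.0909 for each; adjusted p = 0.164, 0.166 and 0.164 with an estimated correlation). Their medians were -1.82, 1.08 and 0.42, against -1.34, 0.82 and 0.43 in the full sets, which held more genes. In OVA against BSA at 20 h 67 of 113 of the set higher with OT cells and 28 of 52 of the lower set were positive (adjusted p = 0.727 and 0.790 with an estimated correlation).

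Ifng, which activated T and NK cells make, stood at 687 and 2147 CPM in DC with OVA and no OT cells, at 23.5 and 0 CPM with OVA and OT cells, at 190.4 and 3.32 CPM with BSA and OT cells and at 13.5 and 0 CPM in the knockout. Camp counts per library were 680 and 703 at 12 h and 2 and 0 at 24 h after CpG-only particles, 111 and 48 at 12 h and 21 and 102 at 24 h after OVA particles, and 11 and 4 without immunization. In several lists the median, the mean and the direction of the test differed in sign, among them chemokines with OT cells and chemokines and cytokines with OVA against CpG-only particles at 12 h. The same held for NK markers at 12 h and 24 h after either particle except CpG-only at 12 h, for cell cycle genes in OVA against no immunization at 20 h (0.02 and -0.08) and for CD8 T cell markers in T cells (-0.08 and 0.28).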
